A study of Mus musculus with 14 samples.

How the data were processed

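RNA from placental tissue of 14 mouse samples was extracted with TRIzol and sequenced as paired-end reads on an MGI-2000 instrument, per the labels' protocols. Per the same protocols, the authors filtered the reads with Trim Galore 0.6.10 and aligned them to the mouse genome build mm39 with STAR 2.7.9a. The submitters' processing notes also name edgeR 4.2.1, DESeq2 1.44.0 and R 4.4.1, without a role for each, and the program that counted reads per gene and the gene annotation are not given in the sources used here. Whether counting used strand is likewise not given, so reads of overlapping or antisense genes, and of near-identical copies, could not be told apart.

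The values came from 2 deposited tables, and every test used the whole-number read counts per gene that the authors deposited, with 54096 genes and 14 columns. The authors also deposited a fold per gene and stage and an unadjusted p-value per gene and stage, whose test is not given in the sources used here; both were set beside the results computed here, and the folds run in the direction of knockout over wild type. A further 28 columns of the longer table, library-size-adjusted counts and FPKM values that the authors deposited, were looked at when the units were identified and entered no result, because only 1 measure of the table was kept for each group. The shorter table held 16035 genes and the FPKM values that the authors deposited, which entered no test, and its folds and p-values were identical to those of the longer table. No line of the count table lacked a gene name.

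The labels give 4 groups from 2 genotypes at 2 stages, with 3 samples per group at E14.5 and 4 per group at E18.5. In the count table the columns are named by stage, by WT or KO, and by number; WT columns were taken as the placentas without Cre and KO columns as those with Cre. A column could be tied to its group but not to a sample, so the replicate numbers used here are those of the columns, and they pair nothing across groups. The title of 1 E18.5 sample with Cre has another format than the titles of the other samples; its column is not known, so a difference in handling of that sample could not be examined. The labels call the replicates biological, and do not say which placentas shared a litter. The protocol text speaks of 3 replicates per genotype, while the labels list 4 per genotype at E18.5, and all of them were used. Totals ran from 28357997 to 34022069 counts per library, and intervals or floors derived from counts cover counting error only.

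Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 4 groups (minimum count 10, minimum total count 15), which left 19048 genes holding at least 99.9% of the counts of every library. Libraries were scaled with TMM. All 14 libraries were fitted together with 1 mean per group and robust quasi-likelihood dispersions (glmQLFit, glmQLFTest), which left 10 residual degrees of freedom. The contrasts were Cre-positive against Cre-negative at E14.5 and at E18.5, the difference between those effects (the interaction), and E18.5 against E14.5 among Cre-negative placentas. Unless another tool is named, an adjusted p is edgeR's quasi-likelihood p after Benjamini-Hochberg adjustment over the 19048 genes, with 0.05 as the threshold, and the error of a log2 fold change is its standard error. Levels are TMM-scaled CPM, as mean ± SD. Where every library of a group was at 0, a fold was computed against a floor of 3 counts over the group and is a lower bound.

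The 30 gene lists, the rule for named genes, the tests and most alternatives were set before the data were examined. The lists come from textbook knowledge and cover interferon and double-stranded RNA responses, stress responses, cell death, placental and other cell types, blood, sex and RNA quality; 647 of their 648 symbols were in the table. Each list was tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the lists within a contrast, and again with a correlation estimated from the data; fry was run beside it. The named genes are Adar; the 10 genes with the highest and the 10 with the lowest log2 fold change (8 and 8 for the interaction and the stage effect) among genes that passed, did not overlap between the groups and reached 1 CPM in the higher group, without unnamed gene models, pseudogenes, Y-linked genes and Xist; up to 4 members with the smallest p of each list described; and a set of genes fixed in advance for double-stranded RNA sensing, interferons, the integrated stress response and trophoblast. Genes called at both stages, and genes of 3 further lists in the closing section, were named after their values were seen.

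Gene positions come from the GENCODE annotation of GRCm39, the assembly that mm39 names, matched by symbol: 125 of the 127 named genes were found, and Doxl2 and Tmem159 are given without a position. Positions count from 1. The deposited table calls the genes of RIG-I and of the glycyl and seryl transfer RNA synthetases Ddx58, Gars and Sars, and those symbols are kept.

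The steps were tested on simulated counts in which 200 genes were changed, 100 of them 2-fold and 100 of them 4-fold. The changed genes were drawn only from genes above a minimum mean count, so recovery among genes with few counts was not measured. At E14.5 the test recovered 45% of the 2-fold and 80% of the 4-fold changes among 18766 genes, with 4.58% of 131 calls false. At E18.5 it recovered 55% and 93% among 18820 genes, with 5.13% of 156 calls false. For the interaction the shares were 33% and 85% among 18651 genes, with 3.28% of 122 calls false. For the stage effect they were 61% and 85% among 18150 genes, with 7.01% of 157 calls false. In the simulated E18.5 contrast camera called a shifted list, and it called 0 of 100 random lists at an unadjusted threshold of 0.05. Genes were simulated independently of each other, so this does not measure false calls in lists whose members move together. In the data the estimated correlation was 0.351 for the interferon-stimulated list and 0.821 for the unfolded protein response list.

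Alternatives changed 1 choice at a time, except that the Wald test of DESeq2 1.42.0 came with its own size factors: DESeq2 size factors, that Wald test, limma voom, no filter or a stricter filter (1 CPM in 3 libraries), only the groups compared, glmQLFit without robust estimation, erythroid and mitochondrial genes left out, the summed Y-linked expression or the erythroid list as a covariate, a minimum log2 fold change of 1 (glmTreat), and each library left out in turn. Library totals without TMM, the 9 libraries with more than 10 CPM over 4 Y-linked genes alone (Y-high libraries; the other E18.5 libraries held 5, 3 and 41 such counts), and covariates for the spongiotrophoblast and decidual lists were added after the data were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.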

Results

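The study sequenced RNA from mouse placentas labelled as having both copies of Adar (Adar1) flanked by loxP sites and as lacking the type I interferon receptor Ifnar. Adar encodes an enzyme that edits adenosines in double-stranded RNA. Placentas without a Cre recombinase (Cre-negative) were set against placentas heterozygous for the allele the labels call Elfcre (Cre-positive), with 3 placentas per genotype at the embryonic stage E14.5 and 4 per genotype at E18.5. The series title gives the purpose as the role of Adar1 in placental innate immunity and in the integrated stress response. Library totals lay between 28357997 and 34022069 counts, and 19048 genes were tested. Replicates of every group differed by more than sampling noise, with a chi-square per degree of freedom of 20.6 to 261 between pairs. The leading principal component held 54.8% of the variance and separated E14.5 libraries (-98.0 to -51.1) from E18.5 libraries (7.86 to 94.2).

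Adar (gene 56417, a protein-coding gene on chromosome 3 of mm39, 89622329 to 89660753) was lower in E14.5 Cre-positive placentas, and was not lower in E18.5 placentas labelled Cre-positive. At E14.5 the Cre-negative libraries held 70.2, 50.4 and 46.8 CPM and the Cre-positive libraries 34.9, 31.5 and 24.0 CPM, a change of -0.89 ± 0.17 (SE) on the log2 scale (adjusted p = 0.0284, n = 3 and 3). At E18.5 the Cre-negative libraries held 45.7, 50.2, 39.1 and 40.5 CPM and the libraries labelled Cre-positive 48.7, 44.5, 49.8 and 46.3 CPM (log2 fold change 0.11 ± 0.14, adjusted p = 0.788, n = 4 and 4). The difference between these effects was 1.00 ± 0.22, adjusted p = 0.117. A count over the whole gene does not show whether the floxed part was transcribed, and placental tissue also holds cells without Cre, so the E18.5 level neither bears out the labels nor excludes deletion. Below, directions at E18.5 rest on the labels alone. The E14.5 call was lost without Cre-negative replicate 1 or 2 (adjusted p = 0.11 and 0.0672), without Cre-positive replicate 2 or 3 (0.0607 and 0.088) and without E18.5 Cre-positive replicate 1 (0.051), which enters the estimate of spread; the log2 change stayed between -0.69 and -0.96 in these fits. It was also lost when only the E14.5 libraries were fitted (adjusted p = 0.0765). In the authors' deposited table the fold of Adar was 0.545 at E14.5 and 1.09 at E18.5, with unadjusted p-values of 0.0252 and 0.71. Ifnar1 was counted in every group, at 103 ± 4.19 (SD, n = 3) and 108 ± 4.24 (n = 3) CPM at E14.5 and at 79.9 ± 1.42 (n = 4) and 88.7 ± 6.0 (n = 4) CPM at E18.5, Cre-negative first. These gene-level counts do not bear out the Ifnar label, and they do not exclude a mutation that leaves the transcript.

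**Figure D1:**
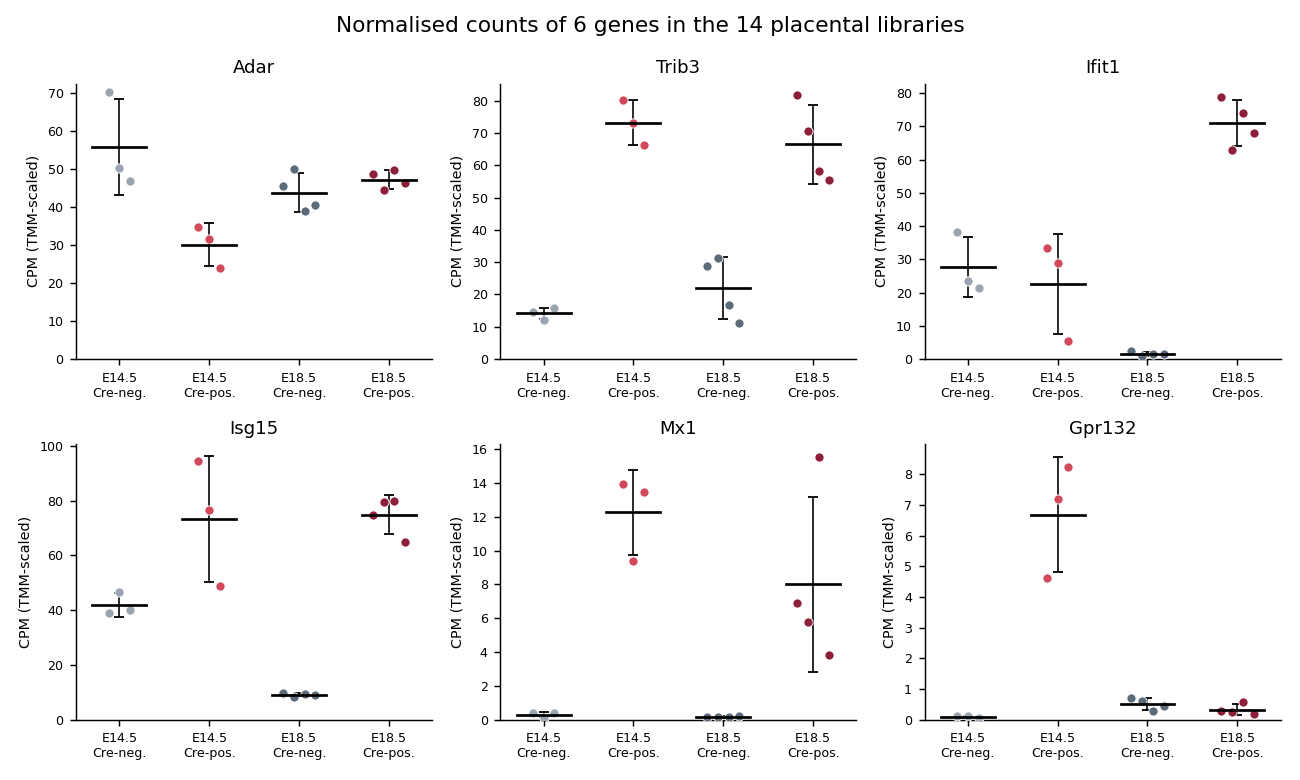
Each point is the TMM-scaled CPM of a gene in 1 library, with 3 libraries per group at E14.5 and 4 at E18.5; horizontal lines give the mean and error bars the SD, on linear axes that start at 0. Adar was lower in the E14.5 Cre-positive libraries, a difference between the stages that did not pass, while Ifit1 rose from 1.63 to 71.1 CPM at E18.5 and Gpr132 from 0.101 to 6.68 CPM at E14.5.

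At E14.5, genes of the antiviral response and of the integrated stress response rose in Cre-positive placentas. Mx1, an antiviral GTPase (chromosome 16, 97248235 to 97264107), went from 0.296 ± 0.157 to 12.3 ± 2.52 CPM (n = 3 and 3), 41.2-fold higher. Trib3, a pseudokinase induced by ATF4 and CHOP (chromosome 2, 152179337 to 152191958), went from 14.2 ± 1.78 to 73.2 ± 6.99 CPM, 5.16-fold higher. Over all genes, 123 rose and 81 fell, and 2696 had an unadjusted p below 0.05. Library totals in place of TMM gave 242 rises and 38 falls.

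Of the 65 tested interferon-stimulated genes, 8 rose, 0 fell and 57 did not pass at E14.5; adjusted over the list alone, 22 rose. Those with the smallest p were Oas1b (1.52 ± 0.16 on the log2 scale, adjusted p = 0.00264), Mx1 (5.36 ± 0.56, adjusted p = 0.00264), Ifi44 (3.05 ± 0.45, adjusted p = 0.00896) and Rsad2 (1.79 ± 0.28, adjusted p = 0.0127), the last of which encodes the antiviral enzyme viperin. The list's median was 0.56 (camera adjusted p = 9.9e-15), and this call was lost with an estimated correlation (adjusted p = 0.419). The list's mean was 4.59 and 4.55 log2 CPM in Cre-positive replicates 1 and 2, and 3.67 in replicate 3. The last value was close to the 3.64, 3.47 and 3.41 of the Cre-negative libraries. Isg15, a ubiquitin-like modifier, did not pass (0.81 ± 0.18, adjusted p = 0.0568), and Ifit1 and Zbp1 had values of -0.30 ± 0.49 and -0.07 ± 0.48. None of the 37 interferon-gamma-type genes or the 21 genes of double-stranded RNA sensing passed edgeR's test (0 of each); adjusted over the list alone, 4 and 3 rose, and DESeq2 called 5 and 3. Their medians were 0.49 (camera adjusted p = 0.00187; adjusted p = 0.642 with an estimated correlation) and 0.29 (0.00782; adjusted p = 0.495 with an estimated correlation). The sensors Ifih1 and Eif2ak2 (PKR) had log2 fold changes of 0.33 ± 0.29 and 0.38 ± 0.22, and the adaptor Mavs 0.07 ± 0.19, none passing.

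Reads of interferon genes were seen in Cre-positive placentas and in none of the 3 E14.5 or 4 E18.5 Cre-negative libraries for Ifnl2, Ifnl3 and Ifnb1. Ifnl2, a type III interferon (chromosome 7, 28208261 to 28209880), had 43, 37 and 1 counts in E14.5 Cre-positive replicates 1, 2 and 3 (81 in all) and 53 over the 4 E18.5 libraries labelled Cre-positive, at least 25.8-fold and 15-fold higher. Ifnl3 had 35, 29 and 0 counts in the same E14.5 libraries (64 in all) and 40 in 4 of 4 E18.5 libraries, at least 20.4-fold and 11.4-fold higher. Ifnl2 and Ifnl3 are near-identical neighbours, so the split of reads between them is uncertain. Ifnb1, a type I interferon, had 20, 9 and 1 counts (30 in all) and 45 in 4 of 4, at least 9.56-fold and 12.8-fold higher. The floor was 3 counts over the group, and none of the 11 tested interferon and receptor genes passed edgeR's test (0 at either stage; 3 and 2 rose when adjusted over the list alone). Camera's adjusted p for that list was 0.0336 at E14.5 and 0.0306 at E18.5, and adjusted p = 0.268 and 0.239 with an estimated correlation. Ifnlr1, which encodes the type III interferon receptor, had log2 fold changes of 0.10 ± 0.13 at E14.5 and 0.13 ± 0.11 at E18.5, neither passing.

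Of the 44 tested targets of the integrated stress response, 11 rose, 0 fell and 33 did not pass at E14.5; adjusted over the list alone, 24 rose. Gars, a transfer RNA synthetase, rose 1.94-fold (log2 0.95 ± 0.13, adjusted p = 0.00607), Ddit4 rose 1.76-fold (0.82 ± 0.13, adjusted p = 0.0135), Ddit3, which encodes CHOP, 1.80-fold (0.85 ± 0.15, adjusted p = 0.0241) and Atf3 1.94-fold (0.96 ± 0.18, adjusted p = 0.0325). Asns and Atf4 did not pass (1.12 ± 0.24, adjusted p = 0.0518; 0.57 ± 0.14, adjusted p = 0.0707). The list's median was 0.54 (camera adjusted p = 3.9e-14), and the call held with an estimated correlation (adjusted p = 0.0498). The endoplasmic reticulum unfolded protein response list went the other way: all 19 members had negative log2 fold changes, with a median of -0.75. None passed edgeR's test over all genes (0 of 19), 4 fell when adjusted over the list alone, and DESeq2 called 3; camera's adjusted p was 1.4e-08, and adjusted p = 0.618 with an estimated correlation. The list's mean was 7.63, 7.82 and 6.83 log2 CPM in the Cre-positive libraries and 8.31, 7.82 and 8.21 in the Cre-negative ones. The lowest value was that of Cre-positive replicate 3, which also had the lowest mean of the spongiotrophoblast list (4.44, against 8.09 to 9.21 in the other E14.5 libraries). Of 29 p53 and cell death genes, only Bbc3, which encodes the pro-apoptotic protein PUMA, rose (1.02 ± 0.20, adjusted p = 0.0348), and 5 rose when adjusted over the list alone (camera adjusted p = 0.00782; adjusted p = 0.618 with an estimated correlation).

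Outside the lists, genes were ranked among those that reached 1 CPM in the higher group without overlap between the groups. The strongest rise at E14.5 was that of Gpr132, a G-protein-coupled receptor (chromosome 12, 112814493 to 112831848). It went from 0.101 ± 0.037 to 6.68 ± 1.87 CPM (63.8-fold higher, log2 SE 0.50, adjusted p = 0.000576). Acod1, the itaconate-producing enzyme, rose by 5.48 ± 1.08 (adjusted p = 0.0348), and Dio3, which inactivates thyroid hormone, by 2.48 ± 0.47 (adjusted p = 0.03). Tmc1, Car6, Cdsn, C1ql2 and the interferon-induced Oasl1 rose by 2.50 to 2.94. By the same rule the deepest falls were Majin (-4.21 ± 0.80, adjusted p = 0.0318), Lypd5 (-4.01 ± 0.63, adjusted p = 0.0131) and Asb10 (-3.02 ± 0.62, adjusted p = 0.0421), with Mybpc3, Izumo1r, Ccdc42, Gdpd2, Sftpd, Ano7 and Zfp385c between -2.64 and -2.13 and Pax5, from the B cell list, at -1.86 ± 0.40.

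Placental composition differed among the E14.5 libraries. Spongiotrophoblast genes took 5.66%, 2.97% and 5.33% of counts in the Cre-negative libraries and 2.09%, 3.48% and 0.242% in the Cre-positive ones, the last in replicate 3. None of the 24 spongiotrophoblast genes passed edgeR's test (0; adjusted over the list alone also 0), and the list's median was -1.32 (camera adjusted p = 2.2e-06; adjusted p = 0.62 with an estimated correlation). Tpbpa, its best known marker (chromosome 13, 61086306 to 61089798), had a log2 fold change of -1.30 ± 0.73 (adjusted p = 0.467). All 17 yolk sac genes had positive values with a median of 1.63 (camera adjusted p = 0.00384; adjusted p = 0.642 with an estimated correlation), and the list mean was 6.06 log2 CPM in Cre-positive replicate 3 against 3.63 and 3.36 in replicates 1 and 2. The Cre-negative libraries held 3.71, 1.66 and 3.77, so Cre-positive replicates 1 and 2 lay below Cre-negative replicates 1 and 3. Cell cycle genes had a median of 0.39, with 25 of 26 positive and 0 passing (camera adjusted p = 1.4e-05; adjusted p = 0.62 with an estimated correlation). Giant cell genes had a median of -0.27 with 0 of 24 passing (camera adjusted p = 0.00384; adjusted p = 0.62 with an estimated correlation).

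Y-linked reads were present in all 3 Cre-negative libraries at E14.5 and in Cre-positive replicate 3 alone, so fetal sex and genotype overlapped. With Y-linked expression as a covariate 194 genes passed, with 4 interferon-stimulated rises in place of 8 and 5 integrated stress response rises in place of 11. The count of 204 genes was 42, 34 and 38 without Cre-negative replicate 1, 2 or 3, and 69 and 72 without Cre-positive replicate 1 or 3. Without E18.5 libraries, which share the estimate of spread, it was 103 and 125 (Cre-positive replicate 1 or 4) and 321 (Cre-negative replicate 4). The 8 interferon-stimulated calls became 2 to 4 without a Cre-negative replicate or Cre-positive replicate 1 or 2, 13 without Cre-positive replicate 3, and 5 without E18.5 Cre-positive replicate 1 or 4. The 11 integrated stress response calls became 2 to 5 without any 1 E14.5 library, and 4 to 6 without E18.5 Cre-positive replicate 1, 3 or 4 or Cre-negative replicate 1. Of the 30 named genes called at E14.5, Gpr132, Mx1, Oas1b, Trib3 and Gars passed in each of the 14 fits that left out 1 library, and the other 25 lost the call in at least 1.

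At E18.5, 51 of 65 interferon-stimulated genes rose in the placentas labelled Cre-positive, and 10 of 19 genes of the endoplasmic reticulum unfolded protein response fell. Isg15 (chromosome 4, 156283883 to 156285303) went from 9.11 ± 0.53 to 74.8 ± 7.05 CPM (n = 4 and 4), 8.21-fold higher, and Ifit1, an RNA-binding antiviral protein (chromosome 19, 34618271 to 34632174), from 1.63 ± 0.59 to 71.1 ± 6.96 CPM, 43.4-fold higher. Pdia4, a protein disulfide isomerase (chromosome 6, 47770077 to 47790462), went from 679 ± 261 to 175 ± 25.5 CPM, 3.88-fold lower. Over all genes, 223 rose and 171 fell, and 3133 had an unadjusted p below 0.05.

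Of the 65 interferon-stimulated genes, 51 rose, 0 fell and 14 did not pass at E18.5; adjusted over the list alone, 60 rose. The smallest p belonged to Isg15 (3.04 ± 0.17, adjusted p = 6.9e-06), Oas1b (2.10 ± 0.14, adjusted p = 2.2e-05), Trim30a (3.33 ± 0.24, adjusted p = 3.2e-05) and Rsad2 (3.48 ± 0.26, adjusted p = 4.4e-05). Ifit3b, Ifit3, Mx1 and Ifit1 had the highest values of the list, 6.06 ± 0.61, 5.70 ± 0.62, 5.49 ± 0.52 and 5.44 ± 0.52; Ifit3 and Ifit3b are close copies, as are Apol9a (4.50 ± 0.86) and Apol9b (4.93 ± 0.68), so their separate counts are uncertain. The list's median was 1.76 (camera adjusted p = 2.2e-69), and the call held with an estimated correlation (adjusted p = 0.0147). Of the 21 genes of double-stranded RNA sensing, 7 rose and 14 did not pass (12 adjusted over the list alone). They included Ddx58 (RIG-I; 1.43 ± 0.14), Zbp1, a sensor of Z-form nucleic acid (4.56 ± 0.49), Dhx58 (3.27 ± 0.35) and Oas2 (3.97 ± 0.45). The median was 0.44 (camera adjusted p = 5.3e-12), and the call held with an estimated correlation (adjusted p = 0.0147). Whether these rises are separate from that of the interferon-stimulated list was not tested. Ifih1 and Eif2ak2 did not pass (1.02 ± 0.25, adjusted p = 0.0576; 0.76 ± 0.20, adjusted p = 0.0695).

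Of the 37 interferon-gamma-type genes, 11 rose and 26 did not pass at E18.5 (20 rose adjusted over the list alone), with Irgm1 (2.27 ± 0.24), Cxcl10 (4.0 ± 0.46), Ifi47 (1.78 ± 0.22) and Igtp (2.08 ± 0.27) leading. The median was 1.03 (camera adjusted p = 3.1e-14; adjusted p = 0.239 with an estimated correlation). Ccl5, a chemokine, rose by 3.22 ± 0.57 as the only called member of 18 inflammatory genes (3 adjusted over the list alone; camera adjusted p = 0.0616). Of 29 p53 and cell death genes, Zbp1 and Bbc3 rose, Bbc3 2.82-fold, and 27 did not pass (4 adjusted over the list alone; camera adjusted p = 0.000164; adjusted p = 0.282 with an estimated correlation). Zbp1 is also a member of the double-stranded RNA sensing list, so its call is counted in both. Acod1 rose by 5.25 ± 0.86.

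All 19 endoplasmic reticulum unfolded protein response genes had negative log2 fold changes at E18.5; 10 fell and 9 did not pass, and 18 fell when adjusted over the list alone. Pdia4 (-1.96 ± 0.28, adjusted p = 0.00364), Manf (-1.39 ± 0.22, adjusted p = 0.00598), Dnajc3 (-1.07 ± 0.20, adjusted p = 0.0154) and Sec61b (-0.74 ± 0.14, adjusted p = 0.0167) led. The median was -1.19 (camera adjusted p = 3.9e-17; adjusted p = 0.239 with an estimated correlation). Of the 44 integrated stress response genes, 2 rose, 1 fell and 41 did not pass; adjusted over the list alone, 8 rose and 2 fell. Trib3 rose 3.02-fold (1.59 ± 0.27, adjusted p = 0.00927) and Sars 1.30-fold (0.37 ± 0.09, adjusted p = 0.0457), while Pycr1, an enzyme of proline synthesis, fell (-1.10 ± 0.17, adjusted p = 0.00582). Sesn2 (0.64 ± 0.15), Atf3 (0.63 ± 0.16), Ddit3 (0.42 ± 0.13), Asns (0.05 ± 0.21) and Atf4 (0.05 ± 0.12) did not pass. The list's median was 0.20 (camera adjusted p = 0.00411; adjusted p = 0.422 with an estimated correlation).

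The libraries labelled Cre-positive at E18.5 held less spongiotrophoblast RNA: 2.02%, 4.42%, 0.975% and 1.60% of counts, against 12.4%, 13.6%, 8.77% and 6.09% in the Cre-negative ones. Of the 24 spongiotrophoblast genes 1 fell, Prl3a1 (-4.57 ± 1.00, adjusted p = 0.0357), and 23 did not pass; adjusted over the list alone, 18 fell and 1 rose. The median was -2.32 (camera adjusted p = 2.4e-09; adjusted p = 0.477 with an estimated correlation), and Tpbpa had a value of -2.19 ± 0.65 (adjusted p = 0.106). Prl5a1 fell among the 24 giant cell genes (-3.57 ± 0.64, adjusted p = 0.0126; 3 adjusted over the list alone; camera adjusted p of the list = 0.0098, and adjusted p = 0.691 with an estimated correlation), while Prl3b1 did not pass (-1.17 ± 0.39). Lgr5 fell among 15 progenitor genes (-1.78 ± 0.36, adjusted p = 0.025; 2 adjusted over the list alone; camera adjusted p of the list = 0.385). Ly6e, the receptor of syncytin A, rose among 19 syncytiotrophoblast genes (1.32 ± 0.23, adjusted p = 0.0125), and 3 of that list rose when adjusted over the list alone; the median was 0.49 (camera adjusted p = 1.4e-05; adjusted p = 0.403 with an estimated correlation). Slc38a2, an amino acid transporter, rose by 0.92 ± 0.15 among 24 transport genes (1 adjusted over the list alone; camera adjusted p of the list = 0.0465, and adjusted p = 0.642 with an estimated correlation). All 12 mitochondrially encoded genes, kept as a list for RNA quality, had negative values at E18.5 with a median of -0.31. Of these, 0 passed edgeR's test, and 1 fell when adjusted over the list alone (camera adjusted p = 0.000666; adjusted p = 0.477 with an estimated correlation). Their mean was 6.4, 6.37, 7.09 and 6.39 log2 CPM in the libraries labelled Cre-positive and 7.03, 6.98, 6.98 and 6.70 in the Cre-negative ones. The other deep falls were Cacna2d3 (-4.91 ± 0.51), Neurog2 (-4.51 ± 0.93), Il21r (-4.26 ± 0.46), Il23r (-3.98 ± 0.64), Enpp7 (-3.58 ± 0.72), Lrrn4 (-3.38 ± 0.49), Acacb (-3.25 ± 0.42) and Rab27a (-3.20 ± 0.47). Macrophage, lymphocyte, neutrophil and B cell lists had medians of -0.20, -0.03, -0.02 and -0.20, with Ccl5 as their only called member.

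The count of 394 genes was 166, 208 and 1415 without Cre-negative replicate 1, 2 or 4, and 167, 218 and 192 without replicate 1, 3 or 4 labelled Cre-positive; library totals in place of TMM gave 1654 rises and 240 falls. The 51 interferon-stimulated calls stayed at 44 to 55 without any 1 library. The 10 falls of the unfolded protein response list became 2, 4, 6 and 16 without Cre-negative replicate 1, 2, 3 or 4, and 2, 4 and 2 without replicate 1, 3 or 4 labelled Cre-positive. The 11 interferon-gamma-type calls became 7 without replicate 1 of either genotype. The 2 rises of the integrated stress response list stayed at 2 without E14.5 Cre-positive replicate 1, became 4 without E14.5 Cre-positive replicate 3 or E18.5 Cre-negative replicate 2, 6 without E18.5 Cre-negative replicate 4, and 1 without any other library. Of the 43 named genes called at E18.5, 9 lost the call in at least 1 of these fits: Apol9a, Prl3a1, Neurog2, Enpp7, Prl5a1, Dnajc3, Sec61b, Sars and Lgr5.

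**Figure D2:**
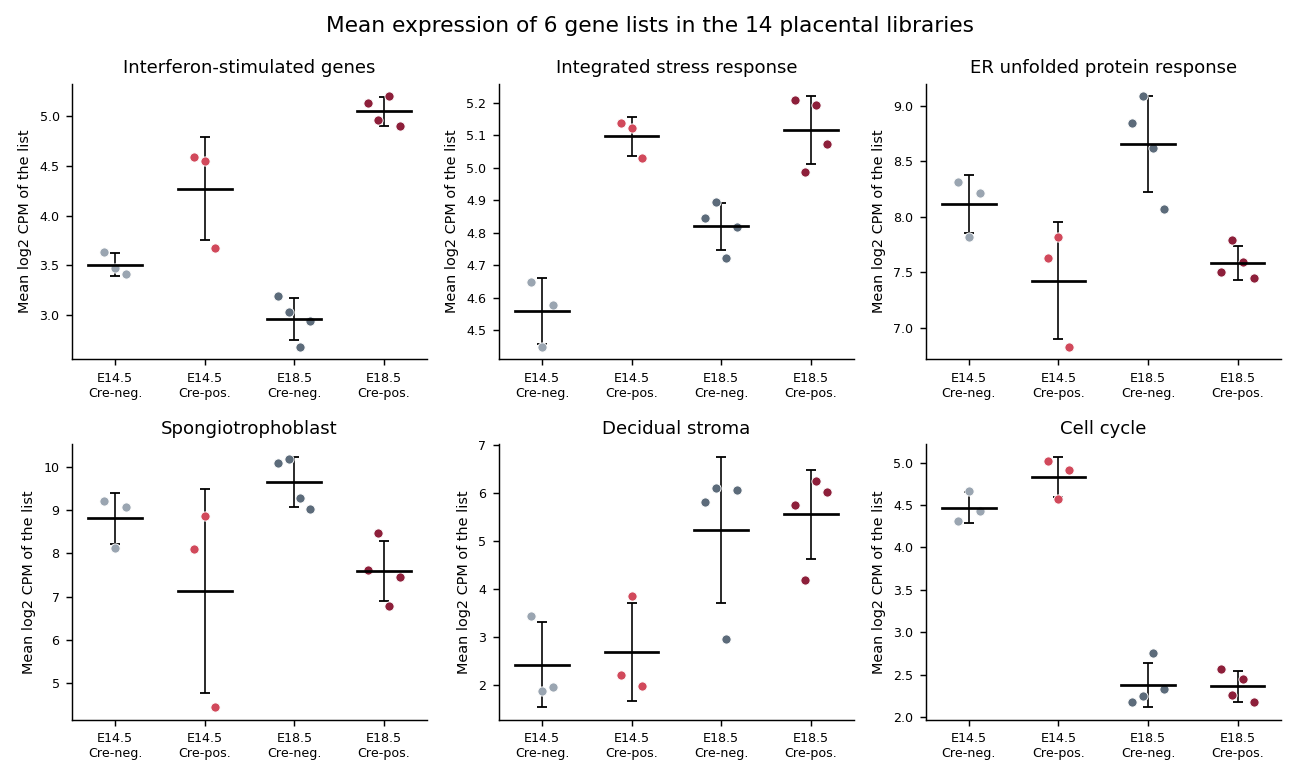
Each point is the mean log2 CPM over the tested members of a gene list in 1 library, with 3 libraries per group at E14.5 and 4 at E18.5; horizontal lines give the mean and error bars the SD, and the vertical axes differ and do not start at 0. The interferon-stimulated list was at 4.90 or more in the E18.5 libraries labelled Cre-positive and at 3.19 or less in the Cre-negative ones, and E14.5 Cre-positive replicate 3 had the lowest spongiotrophoblast mean, 4.44.

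The interaction asked whether the genotype effect differed between the stages, which a call at 1 stage and none at the other does not show. Of the interferon-stimulated genes, 5 of 65 had a larger effect at E18.5: Ifit1 differed by 5.74 ± 0.71 (adjusted p = 0.00982), Trim30a by 3.01 ± 0.34 and Isg15 by 2.23 ± 0.25 (both adjusted p = 0.00412) and Irf9 by 1.00 ± 0.14 (adjusted p = 0.0194). Gpr132 went the other way, with -6.61 ± 0.62 (adjusted p = 0.00255), from its rise at E14.5 to 0.508 and 0.326 CPM in the E18.5 groups. In all, 13 genes had a higher and 3 a lower effect at E18.5, and 1837 had an unadjusted p below 0.05. Zbp1 (4.63 ± 0.67), Trim30d (3.71 ± 0.40), Cmpk2 (2.0 ± 0.30), Castor1 (1.59 ± 0.25) and Tmem159 (1.27 ± 0.20) were among the 13, and Lin9 (-2.47 ± 0.39) among the 3.

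Of the 65 interferon-stimulated genes, 5 differed and 60 did not pass, and 33 differed when adjusted over the list alone; the median was 1.02 (camera adjusted p = 1.1e-33; adjusted p = 0.22 with an estimated correlation). Part of that difference lay in the Cre-negative placentas, where Isg15 was at 41.8 CPM at E14.5 and 9.11 CPM at E18.5 and Ifit1 at 27.7 and 1.63 CPM. In the Cre-positive groups mean Isg15 was 73.1 CPM at E14.5 and 74.8 CPM at E18.5. The difference for Isg15 thus lay almost wholly in the lower Cre-negative level at E18.5. Mean Ifit1 in the Cre-positive groups was 22.5 and 71.1 CPM, so both genotypes contributed to its difference. The integrated stress response list had a median of -0.37 with 0 of 44 genes passing edgeR's test, 7 lower when adjusted over the list alone (camera adjusted p = 1.3e-05; adjusted p = 0.221 with an estimated correlation). For that list the effect at E14.5 was therefore not shown to differ from that at E18.5 gene by gene, and Trib3 differed by -0.77 ± 0.40 (adjusted p = 0.583). The count of 16 genes was 7, 5 and 5 without E14.5 Cre-negative replicate 1, 2 or 3, 5, 6 and 186 without E18.5 Cre-negative replicate 1, 2 or 4, and 7, 7 and 5 without E18.5 replicate 1, 3 or 4 labelled Cre-positive. Irf9, Zbp1, Cmpk2, Tmem159, Lin9 and Castor1 lost the call in at least 1 of these fits.

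At both stages 33 genes rose, against 1.4 for independent lists, and 2 fell (Ssr2 and the gene model Gm44764), against 0.727; Eml2 went in opposite directions. The shared rises included the antiviral genes Mx1, Rsad2, Oas1b, Oasl1, Ifi44, Herc6 and Sp100, the stress genes Trib3, Sars and Gtpbp2, the mitochondrial chaperone and protease Hspa9 and Lonp1, the snoRNA host genes Snhg12 and Snhg16, and Acod1 and Bbc3. Of the 204 genes called at E14.5, 153 had the same sign at E18.5, and 322 of the 394 called at E18.5 had the same sign at E14.5. Across all genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.314 and a Spearman rho of 0.267, and the contrasts shared no library. The overlap of 35 genes was 14, 10, 9 and 16 without E14.5 Cre-negative replicate 1, 2 or 3 or Cre-positive replicate 1, and 16, 74, 15 and 23 without E18.5 Cre-negative replicate 1 or 4 or replicate 1 or 4 labelled Cre-positive.

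**Figure D3:**
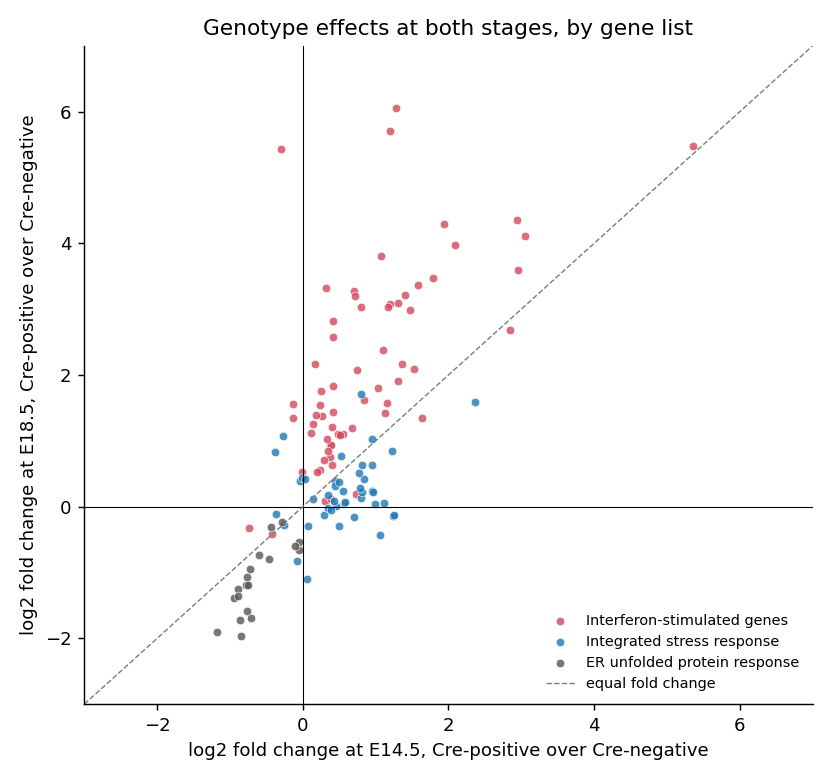
Each point is a tested gene of 3 lists, placed by its log2 fold change of Cre-positive over Cre-negative at E14.5 (horizontal) and E18.5 (vertical); the dashed line marks equal changes. The medians of the interferon-stimulated list were 0.56 and 1.76, those of the integrated stress response list 0.54 and 0.20, and those of the unfolded protein response list -0.75 and -1.19.

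The stage effect among Cre-negative placentas sets E18.5 against E14.5 without Cre. Change over gestation cannot be told apart from a difference in the tissue taken at each stage, such as its share of decidua. Embryonic globins fell from E14.5 to E18.5: Hbb-y (chromosome 7, 103500956 to 103502423) went from 679 ± 433 (n = 3) to 0.577 ± 0.635 CPM (n = 4), and Hba-x and Hbb-bh1 fell by 7.37 and 7.46 on the log2 scale. Prl8a6, a prolactin-family gene, rose from 182 ± 98.5 to 7173 ± 3918 CPM. Over all genes, 3660 rose and 3379 fell. Cell cycle genes fell in 24 of 26 cases, with Mcm5 at -2.93 ± 0.18 and Top2a at -3.23 ± 0.23 (24 also adjusted over the list alone, where 1 rose; camera adjusted p = 3.5e-18; adjusted p = 0.28 with an estimated correlation). Decidual genes rose in 15 of 20 cases, among them Htra1 (3.79 ± 0.79) and Hoxa11 (3.05 ± 0.70), and all 20 were positive (17 adjusted over the list alone; camera adjusted p = 0.000117; adjusted p = 0.669 with an estimated correlation). The decidual list's mean was 5.80, 6.10, 2.96 and 6.06 log2 CPM in E18.5 replicates 1 to 4, so replicate 3 lay below the highest E14.5 library (3.45). Syncytiotrophoblast genes fell in 12 of 19 cases and 1 rose, with Hsd11b2, which inactivates glucocorticoids, at -5.68 ± 0.37 and Syna, which encodes syncytin A, at -3.47 ± 0.58 (12 and 2 adjusted over the list alone; camera adjusted p = 4.8e-05; adjusted p = 0.574 with an estimated correlation).

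Immune and stress lists also moved with stage in Cre-negative placentas. Neutrophil genes rose in 8 of 12 cases, Ltf by 4.70 ± 0.83 and Mmp8 by 3.31 ± 0.54 (10 adjusted over the list alone; camera adjusted p = 0.000269; adjusted p = 0.295 with an estimated correlation). Genes of the list of immediate early and heat shock genes rose in 9 of 14 cases, Fos by 2.08 ± 0.29 (10 adjusted over the list alone, camera adjusted p = 8.1e-05, adjusted p = 0.266 with an estimated correlation). Interferon-stimulated genes fell in 27 of 65 cases and 4 rose, with Isg15 at -2.20 ± 0.18 and Ifit1 at -4.08 ± 0.51 (29 and 4 adjusted over the list alone; camera adjusted p = 0.000134; adjusted p = 0.738 with an estimated correlation). Genes of the interferon-gamma type went the other way, with 15 rising and 2 falling of 37, among them Irf1 (1.94 ± 0.27) and Tgtp1 (4.29 ± 0.75; 16 and 2 adjusted over the list alone; camera adjusted p = 0.00383; adjusted p = 0.738 with an estimated correlation). By the rule for named genes, the highest rises were Doxl2 (9.54 ± 0.88), Slc30a3 (8.34 ± 0.78), Il23r (7.83 ± 1.01), Crct1 (7.39 ± 1.69) and Scn9a (7.28 ± 1.10); Sprr2f, Ces1g and Ffar4 were at 0 in all 3 E14.5 libraries and at least 52.0-fold, 38.9-fold and 35.8-fold higher at E18.5. The deepest falls besides the globins were Izumo1r (-7.32 ± 0.73), Dio3 (-7.13 ± 0.62), Igdcc3 (-6.51 ± 0.49), Slitrk4 (-6.34 ± 0.71) and Tmem72 (-6.05 ± 0.50). The count of 7039 genes was 4460 and 4619 without E14.5 Cre-negative replicate 2 or 3, and library totals in place of TMM gave 2446 rises and 5056 falls.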

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

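The tests of the 3 patterns weighed in this part were chosen after the results were seen. A test for values far from the rest of their group was run on 141 measures in both E18.5 groups (282 tests), and 22 values stood apart; chance alone gives about 1 in 20. For Izumo1r and Slitrk4 the other 3 libraries were at 0, where any count gives the highest possible statistic, so these 3 values show no library standing apart.

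Genotype effects that differed between the stages by the interaction test are listed here as the effect at E18.5 minus that at E14.5 on the log2 scale. Higher at E18.5 were Ifit1 (5.74), Zbp1 (4.63), Trim30d (3.71), Trim30a (3.01), Isg15 (2.23), Cmpk2 (2.0), Castor1 (1.59), Tmem159 (1.27), Meak7 (1.23), Eml2 (1.02), Irf9 (1.00), Tbc1d14 (0.85) and Extl3 (0.75). Lower were Gpr132 (-6.61), Gm44017 (-3.93) and Lin9 (-2.47).

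In E18.5 Cre-negative replicate 3, Apol9a (0.0351 CPM), Irgm1 (17.6 CPM), Top2a (10.5 CPM), the inflammatory cytokine list (1.60 log2 CPM) and the decidual list (2.96 log2 CPM) were far from the other 3 libraries of the group, and Izumo1r (0.0351 CPM) was the only value above 0. In Cre-negative replicate 4 these were Il21r (5.08 CPM), Enpp7 (17.8 CPM), Acacb (12.9 CPM), Tmem159 (19.4 CPM) and the mitochondrial list (6.70 log2 CPM), and Slitrk4 (0.0672 CPM) was the only value above 0. In replicate 2 labelled Cre-positive, Enpp7 (9.36 CPM), Acacb (5.47 CPM), the share of the 10 most abundant genes (8.37%) and principal components 1 and 3 (34.1 and -44.2) stood apart. In replicate 3 labelled Cre-positive it was Irgm1 (151 CPM), the erythroid share (0.429%) and the mitochondrial list (7.09 log2 CPM), with Slitrk4 (0.0613 CPM) as the only value above 0, and in replicate 1 the yolk sac list (4.51 log2 CPM).

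The rise of interferon-stimulated genes at E18.5 was found in placentas labelled Cre-positive whose Adar counts were not lower. Fetal sex as the cause is argued against, because the median log2 fold change of the list was 1.88 among the libraries with more than 10 CPM of Y-linked reads. Library totals gave a list median of 1.99 and moved the median of all genes to 0.22. A shift of that size could not have removed the rise, so only the choice between TMM and totals is argued against. More immune cells are argued against as well, since the highest median of 4 immune cell lists was -0.016. Of the 35 splits of the 8 libraries, 1, the real one, called as many genes of the list as the labels did (51, highest other 5). This argues against chance for the list but does not exclude it. A share of 1 of 35 is the smallest possible, and the test was chosen after the results were seen. An effect of Cre on the floxed Adar gene stays a candidate explanation that these counts do not test, and an altered gene product that leaves the count unchanged was not examined.

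The fall of endoplasmic reticulum chaperones at E18.5 came with a lower share of spongiotrophoblast, a secretory cell type. With the spongiotrophoblast list as a covariate across groups, the median of the chaperone list went from -1.19 to -0.51 and its called falls from 10 to 2, so a change in cell makeup and a change within cells cannot be told apart: the covariate differs between the groups and removes part of any genotype effect. Library totals gave a list median of -0.95 and moved the median of all genes to 0.22, a shift too small to remove the fall. Only the choice between TMM and totals is thus argued against as the whole cause. Of the 35 splits, 1, the real one, called as many falls in the list (10, highest other 7), the smallest share that 35 splits allow. The 7 came from the split that exchanges Cre-negative replicate 4 with replicate 2 labelled Cre-positive, weighed below. Without 1 library the count went as low as 2, and camera with an estimated correlation gave adjusted p = 0.239. Chance is therefore not excluded for this list. Fewer secretory cells, or less chaperone RNA per cell, may each account for it.

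E14.5 Cre-positive replicate 3 stood apart from replicates 1 and 2. Its spongiotrophoblast list mean was lower than theirs by 4.04 log2 units (-4.04) while its syncytiotrophoblast list was higher by 0.35, as a piece with little junctional zone would give, so this explanation may hold. Its interferon-stimulated list mean was 3.67, next to the Cre-negative values of 3.64, 3.47 and 3.41 and below the 4.59 and 4.55 of replicates 1 and 2, as a mislabelled Cre-negative placenta would give. Against mislabelling, its integrated stress response list mean was 5.03, above the highest Cre-negative value of 4.65 by more than their SD of 0.10, and it held 13.5 CPM of Mx1 and 24.0 CPM of Adar, where no E14.5 Cre-negative library had more than 0.390 or less than 46.8. Fetal sex cannot be told apart, since it was the only Cre-positive library with Y-linked reads at E14.5; at E18.5 libraries labelled Cre-positive with more and with less than 10 CPM of such reads differed by -0.0026 in the interferon-stimulated list.

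For the counts over all genes, the splits bear on chance as follows. At E14.5 the real split gave 204 genes and the highest of the others 0, and 10 splits (1 as large) are too few for a share under 0.05. At E18.5 chance cannot be excluded: the real split gave 394 genes and another 792 (2 of 35 as large). That other split exchanges Cre-negative replicate 4 with replicate 2 labelled Cre-positive, and calling that many genes it points to a structure of the samples beside genotype. Principal component 2 was 1.47 to 59.8 in Cre-negative replicates 1, 2 and 3 and replicate 2 labelled Cre-positive. In the other E18.5 libraries it was -61.7 to -28.15. The former all held more than 10 CPM of Y-linked reads, and of the latter only replicate 1 labelled Cre-positive did. What this component stands for was not tested. The split called 5 interferon-stimulated genes and shared 50 genes with the 394. Isg15 was at 9.08 CPM in Cre-negative replicate 4 and 79.6 CPM in replicate 2 labelled Cre-positive, which argues against an exchange of these 2 libraries. For the stage effect only the real split reached its count (real 7039, highest other 5204, 1 of 35), a share under 0.05 and the smallest possible. The split with 5204 genes moves all 3 E14.5 libraries and E18.5 replicates 1, 2 and 4. It is the real stage contrast nearly inverted and shares 4224 of the real calls, so 5204 is no measure of chance. For the interaction chance cannot be excluded (real 16, highest other 917, 7 of 100 splits drawn). Of the interferon-stimulated list the real interaction called 5 genes, and 3 of 100 splits, the real one included, called as many, with up to 13. For the interaction, labels were shuffled within each stage separately, so a split could keep or invert the real labels of 1 stage. Such a split still carries the genotype effect of that stage, so these shares do not measure chance alone.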

How the results depend on the processing

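No paired analysis was possible because the replicate numbers belong to the columns of the count table and pair no placentas. Library totals, the Y-high libraries (over 10 CPM of Y-linked reads) alone and the covariates for spongiotrophoblast and decidual lists were chosen after the data were seen, and so were the alternatives for the overlap other than its thresholds; the cause was not tested for any shift below unless it is named. DESeq2 called 909 genes at E14.5, 1220 at E18.5 and 314 for the interaction, with 19 interferon-stimulated and 19 stress response rises at E14.5, 7 stress response rises at E18.5 and 198 overlapping genes. Voom left 5 interferon-stimulated rises at E14.5, and no filter 125 genes at E14.5. Fitting only the groups compared gave 428 genes at E14.5, 161 at E18.5 and 0 stress response rises at E18.5, from fewer libraries. A minimum log2 fold change of 1, a stricter hypothesis, left 2, 58, 4 and 952 genes (E14.5, E18.5, interaction, stage) and 1 overlapping gene. The sex covariate gave 81 genes for the interaction, with 4 interferon-stimulated and 5 stress response rises at E14.5; the blood covariate gave 4 stress response rises at E18.5. Thresholds of 0.01 and 0.1 gave 7 and 101 overlapping genes. Over the 30 lists and 4 contrasts 47 camera tests passed, 3 with an estimated correlation, and fry called 25, a test that does not compare a list with other genes.

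Library totals moved the median log2 fold change of all genes to 0.13 at E14.5, 0.22 at E18.5 and -0.17 for stage, and changes under them are relative to these shifts: 242 rises and 38 falls at E14.5 (123 and 81 with TMM), 1894 genes at E18.5 (1654 and 240, against 223 and 171), 26 for the interaction, 2446 rises and 5056 falls for stage (3660 and 3379), 17 and 13 stress response rises at E14.5 and E18.5, and an overlap of 133. Y-high libraries, 3 against 1 at E14.5 and 3 against 2 at E18.5, gave 3 and 172 genes, 1 interferon-stimulated and 0 stress response rises at E14.5 and an overlap of 1, from fewer libraries; the 1 at E14.5 was Cre-positive replicate 3, so the E14.5 values do not bear on sex. The spongiotrophoblast covariate within groups gave 679, 898 and 49 genes, 17 interferon-stimulated and 17 stress response rises at E14.5, 5 stress response rises at E18.5 and an overlap of 242; across groups it gave 170 genes at E18.5, 53 for the interaction and 20 interferon-stimulated rises at E14.5. The decidual covariate gave 395 genes at E14.5, 5 stress response rises at E18.5 and an overlap of 66. The 51 interferon-stimulated rises at E18.5 stayed within 1.5 times under the alternatives run for them, which did not include the minimum fold or the fit without robust estimation.

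Leaving out 1 library gave 34 to 321 genes at E14.5, 166 to 1415 at E18.5, 5 to 186 for the interaction and 4460 to 7545 for stage. Interferon-stimulated rises ran from 2 to 13 at E14.5 and from 44 to 55 at E18.5, stress response rises from 2 to 15 and from 1 to 6, and the overlap from 9 to 74. Counts over all genes were highest without E18.5 Cre-negative replicate 4 for the genotype effect at both stages and for the interaction. The same held for the overlap and the stress response rises. The 13 and 55 interferon-stimulated rises came without E14.5 Cre-positive replicate 3. Of the named genes called, 2 of 30 at E14.5 (Gpr132 and Mx1), 21 of 43 at E18.5, 3 of 11 for the interaction and 33 of 37 for stage kept the call under every alternative, and 0 reversed.

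Reversed signs occurred only in named genes that had not passed. At E14.5 these were Ifit1 (from -0.69 to 0.17 without 1 library, with 0.0023 without Cre-negative replicate 1 and 0.17 without Cre-positive replicate 3, and 0.20 with the spongiotrophoblast covariate across groups) and Zbp1 (from -0.40 to 0.33, with 0.22 and 0.33 without the same libraries, 0.018 under library totals, 0.29 with that covariate). Ifih1 (-0.46) and Eif2ak2 (-0.13) reversed among Y-high libraries, Mavs (-0.044 to 0.15) without Cre-positive replicate 1 and Ifnlr1 (-0.0061 to 0.21) without Cre-negative replicate 1. At E18.5 they were Atf4 (-0.034 to 0.13, the lowest without Cre-negative replicate 3) and Asns (-0.098 to 0.21, with -0.098 without Cre-negative replicate 4, -0.026 without Cre-positive replicate 2).

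Depth did not limit the abundant genes, but interferon genes with 30 to 81 counts over a group allow only a lower bound on their fold. With 3 placentas per group at E14.5 the simulated test found 45% of 2-fold changes in genes above a minimum mean count. Changes of that size can thus be missing from the calls, and recovery in genes with few counts was not measured.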

Other observations

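The tests of 3 further gene lists in this part were chosen after the results were seen, with the members that had led to each list left out. Genes that host small nucleolar RNAs, such as Snhg12 and Snhg16, were among those that rose at both stages. Of 11 other host genes, 81.8% had positive values at E14.5, with a median of 0.48 (camera p = 0.015 with an estimated correlation; 1 rose, 4 adjusted over the list alone), and 72.7% at E18.5, with a median of 0.17 (camera p = 0.459). The host genes may therefore move as a group at E14.5, which stays a hypothesis, and the E18.5 value leaves it open. Hspa9 and Lonp1, which serve mitochondrial protein folding and breakdown, also rose at both stages. Of 17 other mitochondrial chaperones and proteases, 58.8% were positive at E14.5, against the idea that the group moved, and 82.4% at E18.5 with a median of 0.06, which leaves it open there.

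Ssr2, a subunit of the complex that assists protein translocation into the endoplasmic reticulum, fell at both stages. All 26 other genes of signal peptide recognition and translocation (100%) had negative values at E14.5 and at E18.5, with medians of -0.36 and -0.38. Of these 0 passed at E14.5 and 3 at E18.5 with edgeR, 6 and 17 adjusted over the list alone, and camera with an estimated correlation gave p = 0.12 and 0.0936. A lower demand for secretion may be shared with the unfolded protein response list, but at E18.5 the libraries labelled Cre-positive held less spongiotrophoblast RNA, and at E14.5 Cre-positive replicate 3 did, and the test did not separate these.

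E18.5 libraries with more than 10 CPM of Y-linked reads also held Xist, which is transcribed from the inactive X chromosome and so marks female, here possibly maternal, cells. Xist was at 67.1, 74.1 and 4.48 CPM in Cre-negative replicates 1, 2 and 3 and at 62.6 and 10.7 CPM in replicates 1 and 2 labelled Cre-positive, and their decidual list means were 5.80, 6.10, 2.96, 5.75 and 4.19 log2 CPM in the same order. The amount of maternal tissue may thus differ between pieces. With the decidual list as a covariate within groups 395 genes passed at E14.5 and 501 at E18.5, so the counts of changed genes depend on it.

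The p-values in the authors' deposited table were larger than those computed here: the median over tested genes was 0.652 and 0.638 at E14.5 and E18.5, against 0.385 and 0.360. Of the genes called here, 91 of 204 and 268 of 394 had a deposited p below 0.05, and all had the same sign in the deposited folds. After Benjamini-Hochberg adjustment of the deposited p-values over all 54096 genes, 0 genes lay below 0.05 at either stage. Before adjustment 440 and 863 did, 334 and 675 of them among the tested genes. The calls made here were adjusted over the 19048 tested genes, so these counts are not like for like. In that table Isg15 had folds of 1.76 and 8.30 and Trib3 of 5.21 and 3.05, and Ifnl2 folds of 217 and 101, which depend on how the authors treated a group with 0 counts.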
